A study of Danio rerio with 12 samples.

How the data were processed

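Messenger RNA was measured by bulk sequencing in 12 samples of 15 whole zebrafish larvae each, 3 samples at each of 4 bepridil doses. Per the labels' protocols, RNA was extracted with RNAiso Plus and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, Trimmomatic, HISAT2 and HTSeq were used with genome build GRCz11, and their versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per gene, which the authors had not normalized as far as the values show (whole numbers with different totals per library). The table of the whole series held 25099 gene names, and the 12 per-sample files held the same counts. Of these genes, 18 had no count in any library, and 10 names had been turned into dates by a spreadsheet and were left as they are. Coordinates and gene lengths were not used here, because the annotation given is of another build.

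Each library was mapped to its dose by the labels, and replicate numbers were taken from the same labels. Within each group, the counts of every pair of libraries differed by more than sampling noise (chi-square over degrees of freedom from 3.795 to 16.74), so no library was counted as a repeat of another. Total counts of 15571556 to 18284169 per library make counting error small beside the spread between replicates for well-counted genes. For genes at a few CPM or less, among them several named below, it is not small. The common dispersion was 0.0146, a coefficient of variation of 12.1% between replicates.

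Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the dose groups, which left 21581, and libraries were scaled by TMM factors. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with dose group as the only factor and 8 residual degrees of freedom. The contrasts were each dose against 0 ng/mL, 750 against 250 ng/mL, 1295 against 750 ng/mL, all 3 coefficients together, and, in a separate fit, a slope on dose per 1000 ng/mL. P-values were adjusted by Benjamini-Hochberg over tested genes and called under 0.05. Fold changes used a prior count of 0.125, and the standard error is the size of the log2 fold change divided by the square root of F. CPM were computed with the TMM factors. The dose groups, tests of doses, gene lists and rule for named genes were fixed before the data were examined, as were the alternatives except those said to have been chosen later.

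Of 40 gene lists written from textbook knowledge of tissues and pathways, 39 had at least 5 tested members. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, beside fry and camera with an estimated correlation, and adjusted over the lists of a contrast. Camera compares a list with all other genes, while fry asks whether its genes move on balance 1 way. Members were counted as higher or lower over all genes and adjusted over the list alone. Some genes stand in more than 1 list, and lists of cell types hold genes that other tissues of a whole larva also express.

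Named genes followed a rule. At each dose they were the 10 with the largest positive and the 10 with the largest negative log2 fold change among genes that passed, had a mean of at least 1 CPM, bore a curated symbol and had all treated libraries on 1 side of all controls. Up to 4 members per list with the smallest p at 1295 ng/mL were added. For the neighbouring doses and the slope, 3 genes per direction were taken, and where none passed, the 5 with the smallest p.

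Overlaps between doses were set beside the overlap of independent lists. They were also set beside 50 simulated experiments without effects, in which the doses shared the same simulated controls. The tests were tried on simulated counts with changed genes planted at 3 sizes. For 250 ng/mL the quasi-likelihood test recovered 37.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, over 21447 genes, and 6.33% of its calls were false. For 1295 ng/mL these shares were 37.3%, 85.1% and 97%, over 21433 genes, and 5.81% of calls were false. For 750 against 250 ng/mL they were 43.3%, 76.1% and 98.5%, over 21434 genes, and 3.33% were false. Camera called the 1 planted list and 0 of 20 unchanged ones. Each gene was simulated on its own, so genes of a list did not move together. In the data, estimated correlations at 250 ng/mL ran from 0.000539 (fatty acid synthesis) to 0.822 (ribosomal proteins). Camera's false calls on correlated lists were therefore not tested. For 1295 ng/mL, 67, 67 and 66 changed genes were planted at the 3 sizes, against 8848 called in the data. The share of false calls need not carry over.

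Alternatives were other scalings (RLE, upper-quartile and total counts only), other filters (no filter, or at least 10 counts in every library), DESeq2 1.42.0, limma-voom, only the compared groups in the fit, a replicate block, stricter thresholds, other dose scales, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.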

Results

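Whole zebrafish larvae of the AB strain were exposed to bepridil, a calcium channel blocker once used against angina, at 0, 250, 750 or 1295 ng/mL. RNA was taken at 120 hours post fertilization, 15 larvae were pooled per sample, and each of the 4 dose groups had 3 samples, so 12 libraries were sequenced. The 0 ng/mL group served as the control. Total counts per library ran from 15571556 to 18284169, and between 23565 and 24102 of the 25099 listed genes had at least 1 count. The labels do not say whether replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. Values of single genes are given as CPM (counts scaled to a common library size with the normalization factors, mean ± SD, n = 3 libraries per dose), and log2 fold changes carry their standard error (SE).

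The 1295 ng/mL libraries stood apart from the other 9. The first principal component held 57.9% of the variance, and on it the 1295 ng/mL libraries lay between -83.63 and -64.43, the controls between -3.56 and 10.45, and the 250 and 750 ng/mL libraries between 18.2 and 48.5. The second component held 10.9% of the variance. On it, 750 ng/mL replicate 3 lay at -39.55, below the other 2 libraries of its group at -7.31 and -2.08. On the first component, 1295 ng/mL replicate 2 lay at -83.63 and the other 2 libraries of its group at -64.43 and -66.42. The 20 most abundant genes took 16.5% to 18.3% of the counts at 1295 ng/mL and 12.7% to 14.2% in the other libraries. The normalization factors were 0.8308 to 0.9055 at 1295 ng/mL and 1.011 to 1.075 elsewhere.

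**Figure D1:**
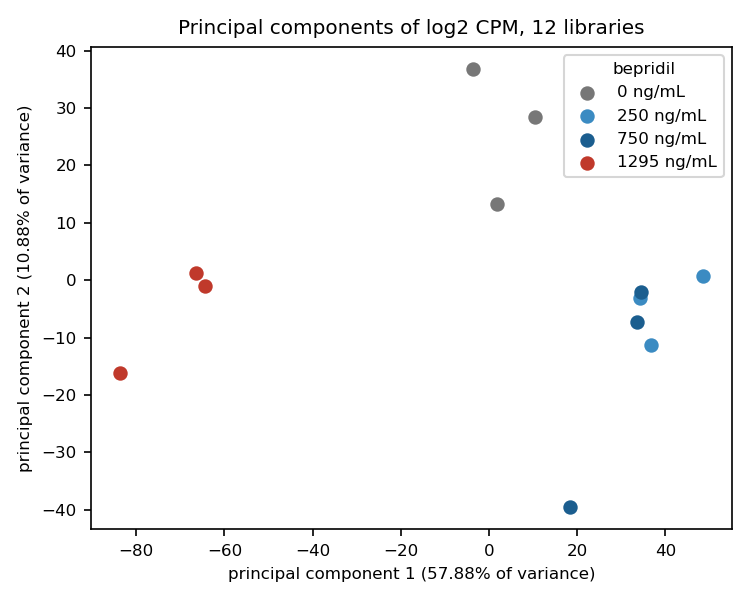
Each point is 1 of the 12 libraries, placed by its first (x axis, 57.9% of variance) and second (y axis, 10.9%) principal component of log2 CPM and coloured by bepridil dose. The 3 libraries at 1295 ng/mL lie below -64 on the first component, and 750 ng/mL replicate 3 lies at -39.55 on the second.

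The first question was what the lowest dose changed against untreated larvae. At 250 ng/mL, 26 of 28 tested exocrine pancreas genes rose and 1 fell, and 30 of 49 enterocyte genes rose and 3 fell. Expression of mep1b, a protease of the intestinal brush border, went from 0.952 ± 0.481 to 9.57 ± 1.09 CPM (log2 fold change 3.32, SE 0.36, adjusted p = 8.9e-05). Expression of cyp3a65, a cytochrome P450 of liver and intestine, went from 46.6 ± 15.4 to 250.1 ± 38.3 CPM (log2 fold change 2.42, SE 0.18, adjusted p = 7.67e-06). The muscle ubiquitin ligase gene fbxo32 rose by 2.54 on the log2 scale (SE 0.34, adjusted p = 0.000372). The D-amino acid oxidase gene dao.1 fell by 3.11 on the log2 scale (SE 0.34, adjusted p = 8.9e-05), from 8.42 ± 1.48 to 0.989 ± 0.711 CPM, and gch2, a GTP cyclohydrolase of pigment synthesis, fell by 2.25 (SE 0.21, adjusted p = 4.69e-05).

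Other genes with large increases at 250 ng/mL were clca1 (log2 fold change 3.03), cbln8 (2.96), ppp1r27b (2.91), upp2, a uridine phosphorylase (2.90), cuzd1.2 (2.84), klhl38b (2.67) and c6ast3, an astacin metalloprotease (2.67), with adjusted p values between 1.15e-05 and 0.00151. The leptin gene lepb had a log2 fold change of 4.71 (SE 1.29, adjusted p = 0.0313) that rested on low and uneven counts, with 1.68, 0.556 and 7.28 CPM in the 3 libraries. Its call was lost without 250 ng/mL replicate 3 (log2 fold change 3.19) and without control replicate 1, 2 or 3 (5.08, 5.12 and 4.13), and also with limma-voom (4.24). Among the decreases, acot17, an acyl-CoA thioesterase, fell by 1.99, the vitellogenin gene vtg7 by 1.98, the cytochrome P450 genes cyp2aa3, cyp2aa9 and cyp2aa8 by 1.96, 1.78 and 1.70, and the zinc transporter gene slc39a5 by 1.82. The matrix gene emilin3a fell by 1.65, and mthfd1l, an enzyme of mitochondrial folate metabolism, fell by 1.39. Adjusted p values of these 8 genes lay between 1.41e-05 and 0.0131. The cyp2aa genes and several others named here have close paralogs, so reads could have been split or shared between copies in counting, and their single values are uncertain.

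By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2269 of 21581 tested genes changed at 250 ng/mL, 1302 higher and 967 lower, and 450 of them changed at least 2-fold. The 57.4% share of higher calls was 45% of 2644 calls with DESeq2, which uses another scaling and test. It was 48.7% with that scaling in edgeR and 45.1% without 750 ng/mL replicate 3, a library left out after the data had been seen. The count was 1105 without control replicate 1 and 1069 without 250 ng/mL replicate 3.

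Digestive gene lists had the smallest camera p values at 250 ng/mL. Of 28 tested exocrine pancreas genes, which encode digestive enzymes and their partners, 26 rose and 1 fell over all genes, and the same numbers held adjusted over the list alone. Their median log2 fold change was 2.07 (camera adjusted p = 6.1e-45; adjusted p = 0.0919 with an estimated correlation). Within this list the trypsin inhibitor gene spink4 rose by 1.12 (SE 0.18, adjusted p = 0.00151) and zgc:92590 by 3.34 (SE 0.42, adjusted p = 0.000255). The lipase gene lipf fell by 0.44 (adjusted p = 0.0194), a call lost without 250 ng/mL replicate 3 or control replicate 2, where its log2 fold change was -0.33 and -0.36. Of 49 enterocyte genes, 30 rose and 3 fell, or 33 and 3 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 1.3e-23; adjusted p = 0.0919 with an estimated correlation). The chitinase gene chia.1 rose by 2.22 (SE 0.17, adjusted p = 7.67e-06) and the peptide transporter gene slc15a1b by 1.39 (SE 0.15, adjusted p = 8.9e-05), while the apolipoprotein gene apoa1a fell by 0.84 (SE 0.14, adjusted p = 0.00161).

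The glucocorticoid, xenobiotic, immediate early and circadian lists passed upward at 250 ng/mL. In the glucocorticoid and stress axis list, 26 of 47 genes rose and 1 fell, or 30 and 2 adjusted over the list alone (median 0.50, camera adjusted p = 2.3e-15; adjusted p = 0.0919 with an estimated correlation). The kinase gene sgk1 rose by 0.98 (SE 0.11, adjusted p = 0.000111), the transcription factor gene cebpd by 0.70 (SE 0.11, adjusted p = 0.00126) and igfbp1a, which encodes an insulin-like growth factor binding protein, by 0.71 (SE 0.15, adjusted p = 0.00676). Of 89 xenobiotic metabolism genes, 27 rose and 8 fell, or 35 and 10 adjusted over the list alone (median 0.29, camera adjusted p = 1.35e-06; adjusted p = 0.23 with an estimated correlation). The rising members included cyp3a65 and cyp2k21 (1.08, SE 0.18, adjusted p = 0.00189), and the falling ones cyp2x7 (-0.82, SE 0.11, adjusted p = 0.000434). Among immediate early genes 15 of 51 rose and 1 fell, or 23 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 1.85e-07; adjusted p = 0.116 with an estimated correlation). Of 46 circadian clock genes 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (median 0.26, camera adjusted p = 3.73e-05; adjusted p = 0.0919 with an estimated correlation), with bhlhe40 up by 0.70 (SE 0.12, adjusted p = 0.00174).

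The cell cycle, proteasome, unfolded protein and heat shock lists passed downward at 250 ng/mL. Of 87 cell cycle and DNA replication genes 0 rose and 27 fell, or 44 lower adjusted over the list alone, with a median of -0.26 (camera adjusted p = 6.78e-17; adjusted p = 0.138 with an estimated correlation). The mitotic kinase gene cdk1 fell by 0.43 (SE 0.10, adjusted p = 0.0108). Of 41 proteasome genes 2 rose and 33 fell, or 2 and 37 adjusted over the list alone (median -0.39, camera adjusted p = 1.69e-16; adjusted p = 0.185 with an estimated correlation). The subunit gene psmb4 fell by 0.40 (SE 0.09, adjusted p = 0.0147), and that call was lost without 250 ng/mL replicate 3 (-0.31). In the unfolded protein and amino acid response list 3 of 52 genes rose and 20 fell, or 5 and 26 adjusted over the list alone (median -0.23, camera adjusted p = 1.85e-07; adjusted p = 0.121 with an estimated correlation). Of 35 heat shock genes 0 rose and 10 fell, or 13 lower adjusted over the list alone (median -0.19, camera adjusted p = 6.7e-07; adjusted p = 0.0919 with an estimated correlation).

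The bone, cartilage and erythrocyte lists passed downward, though most of their members did not pass when adjusted over all genes. Of 35 bone and collagen genes 1 rose and 8 fell (1 and 12 adjusted over the list alone; camera adjusted p = 2.07e-06), of 35 cartilage genes 0 rose and 7 fell (1 and 10; 1.92e-05), and of 39 erythrocyte genes 0 rose and 9 fell (0 and 12; 4.3e-06). With an estimated correlation the adjusted p values were 0.0919, 0.0919 and 0.188. Phototransduction genes rose in 11 of 63 cases and fell in 1 (22 and 2 adjusted over the list alone; camera adjusted p = 1.7e-07; adjusted p = 0.379 with an estimated correlation). Inflammation genes rose in 7 of 51 cases and fell in 2 (9 and 2; 0.000119, and 0.0919 with an estimated correlation), neutrophil genes in 6 of 24 with 1 lower (6 and 1; 0.00559 and 0.276), and macrophage genes in 5 of 36 with 0 lower (5 and 0; 0.000609 and 0.276). Cholesterol synthesis genes rose in 7 of 30 cases and fell in 0 (10 and 0; 0.00031 and 0.234), with msmo1, a sterol oxidase, up by 1.46 (SE 0.16, adjusted p = 8.9e-05). The lists of channels (4 higher and 0 lower of 51, 2 and 0 adjusted over the list alone; camera adjusted p = 0.000548 and 0.506 with an estimated correlation), lens crystallins (5 and 0 of 57, 5 and 0 over the list alone; 0.000986 and 0.628), fatty acid synthesis (5 and 1 of 21, 8 and 1; 0.00636 and 0.0919) and hormones (8 and 1 of 41, 10 and 1; 0.000599 and 0.121) passed upward. Nuclear oxidative phosphorylation genes had a median of -0.13 with 4 higher and 3 lower of 91, or 4 and 2 adjusted over the list alone (camera adjusted p = 9.13e-05; adjusted p = 0.698 with an estimated correlation), and 4 and 7 over all genes when scaled by total counts alone. With fry, the channel, lens and oxidative phosphorylation lists did not pass (adjusted p = 0.0735, 0.138 and 0.297). The neutrophil call was lost without control replicate 3 (camera adjusted p = 0.0593) or 250 ng/mL replicate 1 (0.0611), and the oxidative phosphorylation call without 250 ng/mL replicate 3 (0.0563).

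The next question was what 750 ng/mL changed against untreated larvae. Expression of mep1b was 9.02 ± 2.38 CPM against 0.952 ± 0.481 in controls (log2 fold change 3.24, SE 0.36, adjusted p = 0.000254), and cyp3a65 reached 226.0 ± 25.2 CPM (2.28, SE 0.18, adjusted p = 3.92e-05). The granulin gene grn2 rose by 2.60 (SE 0.29, adjusted p = 0.000254), and calcoco1b rose from 2.89 ± 1.79 to 13.2 ± 2.36 CPM (adjusted p = 0.00107). The gene dao.1 fell by 2.75 (SE 0.33, adjusted p = 0.000319), to 1.25 ± 0.262 CPM. The gene gch2 fell by 2.23 (SE 0.21, adjusted p = 8.65e-05).

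Further increases at 750 ng/mL were those of upp2 (3.01), cbln8 (2.93), cuzd1.2 (2.83), ppp1r27b (2.77), clca1 (2.77) and c6ast3 (2.33), with adjusted p values between 6.66e-05 and 0.00316. The gene cyp2aa8 fell by 1.98, acot17 by 1.92, cyp2aa3 by 1.86, cyp2aa9 by 1.69, slc39a5 by 1.63, emilin3a by 1.47 and mthfd1l by 1.36, with adjusted p values between 3.92e-05 and 0.00775. The gene vtg7 fell by 1.46 (SE 0.38, adjusted p = 0.0319). That call was lost without control replicate 1 (-1.27) or 2 (-1.48), without 750 ng/mL replicate 1 (-1.36), 2 (-1.52) or 3 (-1.54), and with limma-voom (-1.43).

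At 750 ng/mL, 1367 of 21581 genes changed by the same test, 906 higher and 461 lower, and 349 changed at least 2-fold. The count was 631 without control replicate 1, 885 without 750 ng/mL replicate 1 and 837 without 750 ng/mL replicate 3, and it was 813 when only the 2 compared groups entered the fit.

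Digestive gene lists had the smallest camera p values at 750 ng/mL. Of 28 exocrine pancreas genes 25 rose and 0 fell, or 26 and 1 adjusted over the list alone (median 1.82, camera adjusted p = 1.75e-44; adjusted p = 0.107 with an estimated correlation), with spink4 up by 1.12 (SE 0.18, adjusted p = 0.00231). Of 49 enterocyte genes 26 rose and 2 fell, or 32 and 2 adjusted over the list alone (median 0.69, camera adjusted p = 1.7e-27; adjusted p = 0.107 with an estimated correlation), with chia.1 up by 1.99 (SE 0.17, adjusted p = 3.92e-05) and slc15a1b by 1.19 (SE 0.15, adjusted p = 0.000422). Glucocorticoid axis genes rose in 20 of 47 cases and fell in 1, or 22 and 1 adjusted over the list alone (camera adjusted p = 2.75e-12; adjusted p = 0.107 with an estimated correlation), with sgk1 up by 0.74 (SE 0.11, adjusted p = 0.00135). Xenobiotic metabolism genes rose in 25 of 89 cases and fell in 7, or 36 and 8 adjusted over the list alone (camera adjusted p = 4.06e-10; adjusted p = 0.161 with an estimated correlation).

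The lens and phototransduction lists passed upward at 750 ng/mL and the cell cycle list downward, though most of their members did not pass when adjusted over all genes. Of 57 lens genes, most of them crystallins, 15 rose and 0 fell, or 32 and 0 adjusted over the list alone (median 0.48, camera adjusted p = 9.09e-15; adjusted p = 0.207 with an estimated correlation). The lens membrane gene lim2.3 was at 20.1, 18.5 and 25.2 CPM in 750 ng/mL replicates 1, 2 and 3, the highest value being that of the library that lay apart on the second component. Of 63 phototransduction genes 6 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.18e-09; adjusted p = 0.287 with an estimated correlation). Cell cycle genes fell in 11 of 87 cases and rose in 0 (31 lower adjusted over the list alone; 6.58e-14, and 0.207 with an estimated correlation). Bone and collagen genes fell in 8 of 35 cases and rose in 1 (10 and 1 adjusted over the list alone; 1.51e-06 and 0.107). The unfolded protein list had 4 genes higher and 11 lower of 52 (5 and 23 adjusted over the list alone; 1.28e-06 and 0.186), and erythrocyte genes were 0 higher and 6 lower of 39 (0 and 13; 2.53e-06 and 0.207). In the proteasome list 2 genes rose and 2 fell of 41 (2 and 5; 1.64e-07 and 0.389). In the inflammation list 3 of 51 genes rose and 1 fell (19 and 3; 0.000165 and 0.124). In the macrophage list 6 of 36 rose and 0 fell (9 and 0; 0.000133 and 0.231), and in the glia list 6 of 31 rose and 0 fell (7 and 0; 0.00364 and 0.124). Genes of immediate early response rose in 8 of 51 cases and fell in 1 (11 and 1; 0.00175 and 0.287). Hormone genes were 5 higher and 0 lower of 41 (8 and 0; 0.000154 and 0.124), circadian genes 6 and 0 of 46 (11 and 1; 0.00552 and 0.207), neutrophil genes 3 and 1 of 24 (6 and 1; 0.00895 and 0.287) and fatty acid synthesis genes 4 and 0 of 21 (7 and 2; 0.0205 and 0.124). Lists that passed downward were cartilage, with 1 higher and 3 lower of 35 (2 and 8; 0.000144 and 0.124), heat shock, with 0 and 4 of 35 (0 and 6; 0.00331 and 0.231), and epidermis, with 6 and 6 of 51 (7 and 14; 0.0205 and 0.541). In these parentheses, the counts are those adjusted over the list alone, followed by the camera adjusted p and the adjusted p with an estimated correlation. Ribosomal protein genes had a median of 0.17 with 0 of 82 passing singly, by either adjustment (camera adjusted p = 2.26e-06; adjusted p = 0.683 with an estimated correlation). With fry, the phototransduction, epidermis, proteasome and ribosomal protein lists did not pass (adjusted p = 0.053, 0.283, 0.0692 and 0.151). The epidermis call was lost without control replicate 2 (camera adjusted p = 0.237) or 750 ng/mL replicate 1 (0.113). The neutrophil and immediate early calls were lost without control replicate 3 (0.103 and 0.0652).

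The highest dose, 1295 ng/mL, was asked the same question. Of 51 inflammation genes 33 rose and 0 fell, and of 89 neuron and synapse genes 0 rose and 75 fell. The interleukin gene il11a went from 0.35 ± 0.158 to 4.36 ± 2.69 CPM (log2 fold change 3.62, SE 0.60, adjusted p = 0.000349). The AP-1 transcription factor gene fosl1a went from 8.77 ± 2.25 to 49.0 ± 8.33 CPM (2.48, SE 0.25, adjusted p = 9.88e-06), and the chemokine gene cxcl8b.1 rose by 2.62 (SE 0.45, adjusted p = 0.000402). In 1295 ng/mL replicates 1, 2 and 3, il11a was at 5.88, 1.25 and 5.93 CPM, cxcl8b.1 at 10.8, 3.36 and 11.6 CPM, and the heat shock gene hsp70l at 29.2, 9.22 and 29.5 CPM. The pacemaker channel gene hcn4 fell by 2.39 (SE 0.46, adjusted p = 0.00103), from 1.90 ± 0.491 to 0.36 ± 0.205 CPM. The photoreceptor and neuronal cation exchanger gene slc24a2 fell by 2.18 (SE 0.28, adjusted p = 6.06e-05), from 8.95 ± 2.403 to 1.97 ± 0.65 CPM.

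Further increases at 1295 ng/mL were led by the hatching enzyme gene he1a, which went from 0.274 ± 0.156 to 27.6 ± 18.4 CPM (log2 fold change 6.64, SE 0.79, adjusted p = 3.3e-05), with 36.3, 6.45 and 40.2 CPM in the 3 libraries. The leptin gene lepb had a log2 fold change of 5.36 (SE 1.23, adjusted p = 0.00312) over libraries at 7.62, 0.329 and 7.17 CPM, and limma-voom did not call it (4.72). The genes plekhs1 (3.36), ms4a17a.12 (3.12), ms4a17a.4 (3.04), the embryonic globin gene hbae5 (2.89) and the heat shock gene hsp70l (2.39) rose with adjusted p values between 1.52e-05 and 0.00032. The last 4 of these belong to families of close copies whose reads could be shared in counting. The keratin gene krt93 fell by 2.60, the delta opioid receptor gene oprd1a by 2.29 and cacng5b by 2.29. The transglutaminase gene tgm1l3 fell from 14.4 ± 2.93 to 2.53 ± 0.884 CPM. The genes rnf34b and st8sia7.1p each fell by 2.17, the mitofusin gene mfn1a by 2.15 and vwa5b1 by 2.13. Adjusted p values of these 8 genes lay between 3.95e-06 and 0.00164.

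By the same test 8848 of 21581 genes changed at 1295 ng/mL, 4058 higher and 4790 lower, and at least 2-fold changes were 311 higher and 1619 lower. Without 1295 ng/mL replicate 2, 6729 genes were called. Scaling by total counts alone moved the median log2 fold change of all genes from -0.02 to -0.27 and the share of higher calls from 45.9% to 14.5%, so the changes of groups are given relative to the main scaling.

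Nervous system and retina genes fell as groups at 1295 ng/mL. Scaling by total counts alone lowers the log2 fold changes at this dose, so their fall under it is no separate check. Of 89 neuron and synapse genes 0 rose and 75 fell, or 77 adjusted over the list alone, with a median of -0.91 (camera adjusted p = 4.87e-30; adjusted p = 0.107 with an estimated correlation). The glutamate receptor gene gria4b fell by 1.64 (SE 0.14, adjusted p = 4.57e-06) and gad2, which encodes an enzyme of GABA synthesis, by 1.44 (SE 0.12, adjusted p = 3.95e-06). The list of calcium, potassium and sodium channel and exchanger genes is not limited to nervous tissue. Of its 51 genes 1 rose and 39 fell, or 1 and 42 adjusted over the list alone (median -0.94, camera adjusted p = 1.53e-15; adjusted p = 0.131 with an estimated correlation). The sodium channel gene scn1lab fell by 1.59 (SE 0.17, adjusted p = 1.33e-05), and cacna1c, the pore subunit of the cardiac L-type calcium channel, fell by 1.41 (SE 0.16, adjusted p = 2.24e-05), from 73.0 ± 4.65 to 27.4 ± 7.97 CPM. Of 63 phototransduction genes 1 rose and 47 fell, or 2 and 48 adjusted over the list alone (median -1.02, camera adjusted p = 6.44e-12; adjusted p = 0.254 with an estimated correlation), among them the rod phosphodiesterase gene pde6b (-1.52, SE 0.18, adjusted p = 3.57e-05). In the glia and myelin list 4 of 31 genes rose and 17 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00381; adjusted p = 0.114 with an estimated correlation), and the myelin gene mag fell by 1.24 (SE 0.14, adjusted p = 2.19e-05).

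The inflammation, neutrophil, macrophage and immediate early gene lists passed upward at 1295 ng/mL. Scaled by total counts alone, they had 28 and 0, 12 and 0, 15 and 2, and 23 and 11 genes higher and lower. They also passed camera under that scaling, but this adds no support. Camera compares a list with all other genes, so a change of scaling hardly moves it, and it kept 26 of the lists there. Of 51 inflammation genes 33 rose and 0 fell, or 38 and 0 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 6.36e-15). This was the 1 list of 39 that also passed with an estimated correlation (adjusted p = 0.0145). The prostaglandin synthase gene ptgs2b rose by 1.43 (SE 0.13, adjusted p = 5.58e-06). Of 24 neutrophil genes 17 rose and 0 fell, or 19 and 0 adjusted over the list alone (median 0.70, camera adjusted p = 4.49e-08; adjusted p = 0.107 with an estimated correlation), and the lysozyme gene lyz rose by 0.71 (SE 0.12, adjusted p = 0.000421). Of 36 macrophage genes 19 rose and 1 fell, or 21 and 1 adjusted over the list alone (median 0.69, camera adjusted p = 2.95e-07; adjusted p = 0.139 with an estimated correlation), with apoeb, a lipid carrier gene of microglia and other cells, up by 1.39 (SE 0.13, adjusted p = 6.47e-06). Immediate early genes rose in 31 of 51 cases and fell in 8, with the same numbers adjusted over the list alone (median 0.60, camera adjusted p = 1.52e-07; adjusted p = 0.131 with an estimated correlation). In that list junba rose by 1.80 (SE 0.20, adjusted p = 1.81e-05), while the neuropeptide precursor gene vgf fell by 0.99 (SE 0.11, adjusted p = 1.53e-05).

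The ribosomal protein and oxidative phosphorylation lists passed upward at 1295 ng/mL. Scaled by total counts alone, 77 ribosomal protein genes rose and 1 fell (median 0.36). Of 82 cytosolic ribosomal protein genes 81 rose and 0 fell, and 81 and 0 adjusted over the list alone (median 0.62, camera adjusted p = 6.35e-33; adjusted p = 0.209 with an estimated correlation), with rpl15 up by 0.70 (SE 0.09, adjusted p = 6.49e-05). Of 91 nuclear oxidative phosphorylation genes 78 rose and 1 fell, or 82 and 1 adjusted over the list alone (median 0.51, camera adjusted p = 3.83e-20; adjusted p = 0.254 with an estimated correlation), against 43 and 3 by total counts (median 0.25), with cox8a up by 0.66 (SE 0.10, adjusted p = 0.000134). Of 41 proteasome genes 31 rose and 1 fell, or 34 and 1 adjusted over the list alone (camera adjusted p = 3.3e-08; adjusted p = 0.341 with an estimated correlation), and 4 rose and 1 fell when scaled by total counts alone. Of 59 liver genes 39 rose and 3 fell, or 40 and 3 adjusted over the list alone (median 0.58, camera adjusted p = 1.62e-11; adjusted p = 0.202 with an estimated correlation), with the fibrinogen gene fgb up by 1.17 (SE 0.12, adjusted p = 1.43e-05). Of 51 epidermis genes 31 rose and 3 fell, or 32 and 3 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.139 with an estimated correlation), and the claudin gene cldne rose by 0.92 (SE 0.07, adjusted p = 3.95e-06).

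Stress response lists passed upward at 1295 ng/mL. Of 44 genes of p53 targets and apoptosis 24 rose and 2 fell, or 28 and 3 adjusted over the list alone (camera adjusted p = 2.49e-07; adjusted p = 0.114 with an estimated correlation), with the BH3-only gene pmaip1 up by 1.44 (SE 0.15, adjusted p = 1.13e-05). Of 35 oxidative stress genes 20 rose and 2 fell, or 21 and 3 adjusted over the list alone (1.84e-06 and 0.114), with the heme oxygenase gene hmox1a up by 1.48 (SE 0.14, adjusted p = 6.69e-06). Lysosome genes rose in 35 of 77 cases and fell in 4 (36 and 4 adjusted over the list alone; 1.13e-07 and 0.107), heat shock genes in 18 of 35 with 0 lower (19 and 0; 8.87e-05 and 0.142), and unfolded protein genes in 21 of 52 with 1 lower (23 and 1; 2.1e-05 and 0.209). Of 47 fast muscle genes 26 rose and 8 fell (27 and 8; camera adjusted p = 7.13e-05; adjusted p = 0.403 with an estimated correlation), while the giant sarcomere protein genes neb and ttn.2 fell by 0.82 and 1.37 (adjusted p = 7.16e-05 and 8.16e-06). Scaled by total counts alone, the p53 list was 12 higher and 6 lower, the oxidative stress list 9 and 4, the lysosome list 20 and 12, the heat shock list 7 and 3, the unfolded protein list 8 and 6, and the fast muscle list 18 and 11. Their medians were then 0.10, 0.11, 0.00377, 0.0278, 0.000577 and 0.11 in that order, so the lysosome, heat shock and unfolded protein medians lay close to 0.

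Some lists that passed upward at 1295 ng/mL had a median below 0 when scaled by total counts alone. For cell cycle genes 33 rose and 2 fell of 87, and 33 and 2 adjusted over the list alone (camera adjusted p = 2.92e-05; adjusted p = 0.404 with an estimated correlation), against 4 higher and 13 lower by total counts. Erythrocyte genes went from 15 higher and 6 lower of 39 to 8 and 12. Bone and collagen genes went from 9 and 3 of 35 to 3 and 10, and lens genes from 17 and 1 of 57 to 3 and 5. Slow muscle genes went from 9 and 1 of 19 to 4 and 4, and ionocyte and kidney genes from 19 and 10 of 46 to 14 and 18. Adjusted over the list alone, these 5 lists had 15 and 7, 8 and 3, 7 and 1, 9 and 1, and 19 and 14 genes higher and lower. Their camera adjusted p values were 0.0155, 0.0332, 0.011, 0.0155 and 0.0237, and 0.431, 0.335, 0.59, 0.49 and 0.243 with an estimated correlation. Each of these 5 calls was lost when 1 library was left out. Without control replicate 3 the adjusted p was 0.0549 for erythrocytes, 0.0549 for bone and collagen and 0.0671 for ionocytes and kidney. Without 1295 ng/mL replicate 2 it was 0.158 for slow muscle, 0.0719 for bone and collagen and 0.0634 for lens genes, and without control replicate 1 it was 0.087 for lens genes. The lens list did not pass with fry (adjusted p = 0.174). The glucocorticoid list had 21 genes higher and 5 lower of 47 (22 and 5 adjusted over the list alone; 0.00157, and 0.318 with an estimated correlation) and 9 and 9 by total counts, with a median of 0.06. Cholesterol synthesis genes were 5 and 0 of 30 (4 and 0; 0.00765 and 0.354), and 3 and 2 by total counts, with a median of 0.00362. Scaled by total counts alone, the bone and collagen list did not pass camera (adjusted p = 0.0668). In the lens list, cryba1a was at 0.248, 0.659 and 358.2 CPM in the 3 libraries. Without 1295 ng/mL replicate 3 its log2 fold change went from 7.93 to -0.10, while limma-voom did not call it (3.07).

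Digestive gene lists did not pass at 1295 ng/mL. Of 28 exocrine pancreas genes 2 rose and 0 fell, and 2 and 0 adjusted over the list alone (camera adjusted p = 0.7). Of 49 enterocyte genes 13 rose and 20 fell, or 14 and 22 over the list alone (camera adjusted p = 0.392), with chia.1 down by 1.31 (SE 0.17, adjusted p = 6.53e-05) and apoa1a up by 1.17 (SE 0.14, adjusted p = 3.41e-05). Xenobiotic metabolism genes were 24 higher and 22 lower of 89, or 25 and 23 over the list alone (camera adjusted p = 0.7). Circadian genes were 8 and 14 of 46, or 8 and 15 (0.698). The calcium store list had 10 genes higher and 18 lower of 54, or 10 and 19 (0.0862). Cardiac muscle genes were 10 and 4 of 23, or 10 and 4 (0.148), and endothelial genes 8 and 7 of 38, or 8 and 8 (0.435). The list of fatty acid oxidation and PPAR targets had 12 genes higher and 7 lower of 49, or 12 and 7 (0.0737). That of vitellogenins and egg proteins had 3 and 0 of 7, or 3 and 0 (0.346). Scaled by total counts alone, the counts higher and lower were 8 and 33 for xenobiotic metabolism, 3 and 24 for the circadian clock, 5 and 32 for calcium stores, 3 and 4 for cardiac muscle, 3 and 12 for endothelium, and 5 and 15 for fatty acid oxidation and PPAR targets. They were 2 and 1 for the exocrine pancreas, 10 and 25 for enterocytes, and 1 and 1 for vitellogenins and egg proteins. The cartilage list had 2 genes higher and 11 lower of 35, and 2 and 11 adjusted over the list alone (camera adjusted p = 0.0667), against 1 and 22 by total counts. The calcium store and cartilage lists passed camera under that scaling, and both passed downward with fry (adjusted p = 0.000157 and 0.00396). Fatty acid synthesis genes were 4 higher and 5 lower of 21, or 4 and 5 over the list alone (0.59), and hormone genes 7 and 10 of 41, or 8 and 10 (0.942). By total counts these were 4 and 6, and 3 and 16. The vitellogenin list passed upward with fry (adjusted p = 0.0491). Some of these lists passed camera when 1 library was left out. Cartilage passed downward without control replicate 2 (adjusted p = 0.0384) or 3 (0.045) or 1295 ng/mL replicate 2 (0.0117), and enterocytes downward without control replicate 3 (0.045). Cardiac muscle passed upward without control replicate 2 (0.0302). The fatty acid oxidation list passed upward without control replicate 2 (0.011) or 1295 ng/mL replicate 1 (0.0338) or 3 (0.0404).

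**Figure D2:**
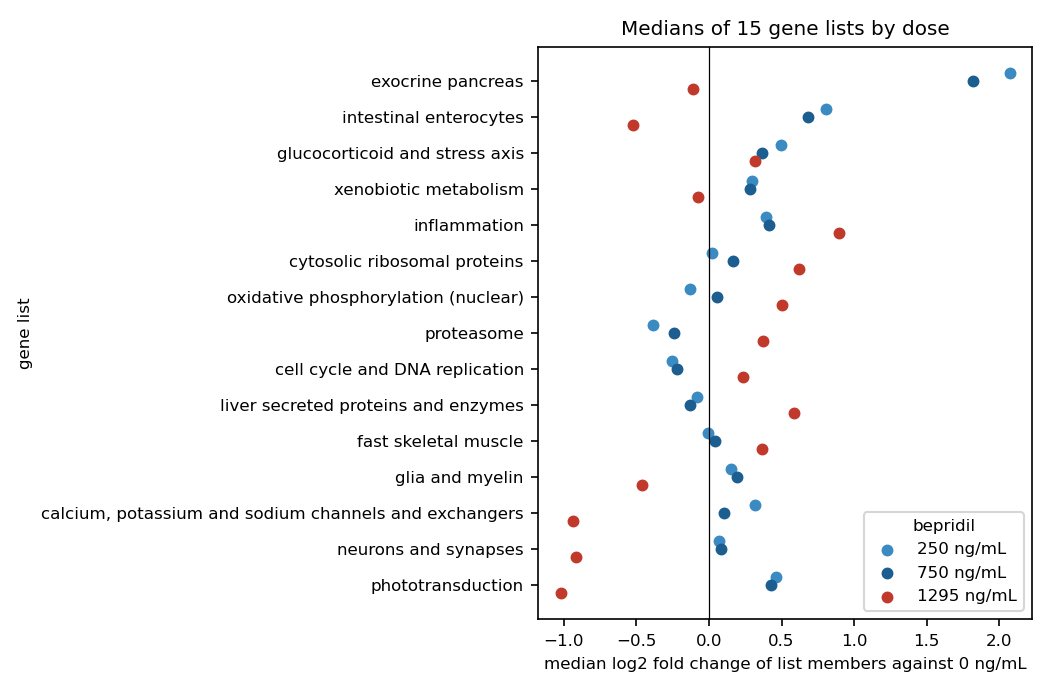
Each point is the median log2 fold change (x axis) of the tested members of 1 gene list (y axis) at 250, 750 or 1295 ng/mL against 0 ng/mL, for 15 lists, under the main scaling. Pancreas medians lie at 2.07 and 1.82 at the lower doses and -0.11 at 1295 ng/mL, where neuron, channel and phototransduction medians lie between -1.02 and -0.91; the cell cycle median at 1295 ng/mL falls below 0 when scaled by total counts alone.

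**Figure D3:**
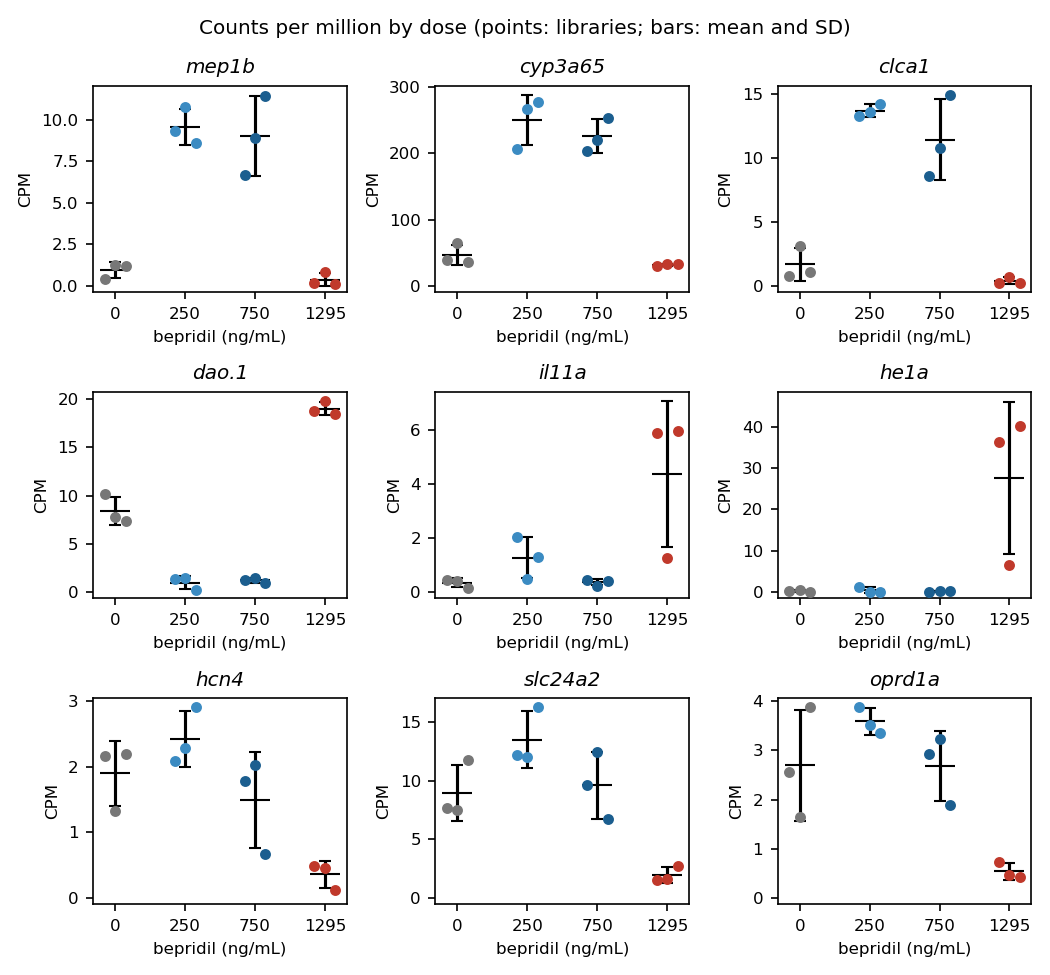
CPM (y axis, linear, from just below 0) against bepridil dose (x axis, ng/mL, doses evenly spaced) for 9 named genes; points are libraries, horizontal bars are means of 3 libraries and vertical bars are SD. The means of mep1b, cyp3a65 and clca1 are highest at 250 and 750 ng/mL, dao.1 is lowest there, il11a and he1a are highest at 1295 ng/mL, and hcn4, slc24a2 and oprd1a are lowest at 1295 ng/mL.

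Neighbouring doses were then compared directly. Between 750 and 250 ng/mL, the genes with the smallest p values were ldlra, the low density lipoprotein receptor gene, at 111.4 ± 6.93 CPM for 250 ng/mL and 79.5 ± 3.85 CPM for 750 ng/mL, and socs2, a suppressor of cytokine signalling, at 39.2 ± 1.12 and 23.4 ± 5.29 CPM. Their log2 differences of -0.49 (SE 0.09) and -0.74 (SE 0.14) each had an adjusted p of 0.619, as did those of dsg2.1 (-0.43), wu:fc34e06 (-0.77) and dnaja (0.50). No gene passed by edgeR's quasi-likelihood test (0 of 21581), 1681 genes had an unadjusted p under 0.05, DESeq2 called those 5 genes and limma-voom called 0. Without 750 ng/mL replicate 3 the pancreatic list member zgc:92590, chosen here after its values were seen, was called (-2.14, adjusted p = 0.0317). In the same comparison 13 lists passed camera with small medians, led by nuclear oxidative phosphorylation (median 0.19, 0 of 91 genes called, camera adjusted p = 3.25e-21; adjusted p = 0.647 with an estimated correlation), and 0 passed with an estimated correlation or with fry.

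Between 1295 and 750 ng/mL, 25 of 28 exocrine pancreas genes and 29 of 49 enterocyte genes fell. The gene clca1 fell by 4.81 (SE 0.45, adjusted p = 1.29e-06), mep1b by 4.54 (SE 0.43, adjusted p = 1.56e-06) and krt93 by 4.07 (SE 0.39, adjusted p = 1.66e-06). The gene he1a rose by 7.07 (SE 0.83, adjusted p = 9.5e-06), dao.1 by 3.92 (SE 0.32, adjusted p = 4.92e-07) and lepb by 4.77 (SE 1.15, adjusted p = 0.00292), though limma-voom did not call lepb (3.94). Of 28 exocrine pancreas genes 1 rose and 25 fell, and 1 and 25 adjusted over the list alone (median -1.86, camera adjusted p = 1.24e-09; adjusted p = 0.25 with an estimated correlation). Of 49 enterocyte genes 6 rose and 29 fell (6 and 29; 3.34e-08 and 0.227). Of 89 neuron genes 1 rose and 73 fell (1 and 74; 1.17e-22 and 0.155), and of 87 cell cycle genes 67 rose and 1 fell (70 and 1; 4.78e-12 and 0.227). Of 27 lists that passed in this comparison, 0 passed with an estimated correlation. By edgeR 11239 of 21581 genes differed, 5054 higher and 6185 lower at 1295 ng/mL. The share of higher calls was 45%, and 21.6% when scaled by total counts alone.

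Across the 4 doses, 11918 of 21581 genes differed in at least 1 group by the quasi-likelihood test on 3 coefficients. A linear dose slope was called for 4724 genes, 2251 upward and 2473 downward. A called slope does not mean a steady change with dose. For example, slc24a2 was at 7.656, 7.463 and 11.72 CPM in controls and at 12.15, 12.05 and 16.29 CPM at 250 ng/mL. At 1295 ng/mL it was at 1.548, 1.646 and 2.719 CPM. The steepest named slopes per 1000 ng/mL were those of cryba1a (7.26, SE 1.37, adjusted p = 0.0119), he1a (6.005, SE 0.85, adjusted p = 0.0111) and crybb3, also a crystallin gene (3.00, SE 0.80, adjusted p = 0.0246), and, downward, hcn4 (-1.68), slc24a2 (-1.61) and oprd1a (-1.54), with adjusted p values of 0.0204, 0.0251 and 0.0253. Each of these 6 calls was lost when 1 or more libraries at 1295 ng/mL were left out singly. Without 1295 ng/mL replicates 1, 2 and 3 in turn the slopes were -1.62, -1.57 and -1.36 for hcn4, -1.32, -1.32 and -1.50 for slc24a2 and -1.42, -1.27 and -1.27 for oprd1a. They were 3.39, 3.44 and -0.17 for crybb3, and none of these 4 genes was then called. The he1a call was lost without 1295 ng/mL replicate 1 (5.47) or 3 (5.35), and the cryba1a call without replicate 1 (7.63) or 3 (0.14). With limma-voom the slopes of cryba1a (2.56) and crybb3 (1.07) were not called. Slope calls numbered 2, 125 and 4 without 1295 ng/mL replicate 1, 2 and 3, 2690 without 250 ng/mL replicate 1 and 2915 without 250 ng/mL replicate 2. They numbered 547 with dose ranks and 8 with a log2 dose scale in place of the linear one. The 47.7% share of rising slopes was 11.7% when scaled by total counts alone.

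The overlap of calls was counted between doses. At 250 and 750 ng/mL, 697 genes were higher at both doses and 336 lower at both, and 0 changed in opposite directions. Independent lists would share 54.7 and 20.7, with 68.4 opposite. Experiments simulated without effects, with simulated controls shared by both doses, shared 0.02 on average. That value is near 0 by construction, because without effects almost no gene is called. Over all tested genes, which are not independent replicates, the log2 fold changes of the 2 doses correlated at r = 0.802, against 0.497 in the simulated experiments, and their covariance was 0.116 against 0.0248, a difference of 0.091. Between 250 and 1295 ng/mL, 234 genes changed in the same direction and 925 in opposite directions, where independent lists would give 245 and 215 in the same direction and 471 opposite. Their covariance was -0.0421 against a simulated 0.0249, a difference of -0.067. For 750 and 1295 ng/mL these counts were 189 and 509, where independent lists would give 170 and 102 in the same direction and 288 opposite, and the covariance of -0.0145 against 0.0248 made a difference of -0.0393. Simulated experiments shared 0.06 and 0.02 genes on average for these pairs of doses, again near 0 by construction. The 3 controls were too few to split, so part of the likeness of 250 and 750 ng/mL may come from the shared controls. For the pairs with 1295 ng/mL they may have changed the size of these values. Simulated shared controls made the covariance positive on average (0.0249 and 0.0248). That argues against gene-by-gene noise in them as the source of the negative covariances of -0.0421 and -0.0145.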

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

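Leaving out 750 ng/mL replicate 3 from the counts at 250 and 1295 ng/mL was chosen after seeing the data; the other settings were planned. Under the other scalings, filters, limma-voom and DESeq2, the counts of called genes at 250, 750 and 1295 ng/mL, between 1295 and 750 ng/mL, across doses and for the slope stayed within 1.5 times the value reported. Similar counts did not mean the same genes. Scaled by total counts alone, 6191 of the 8848 genes reported at 1295 ng/mL were called again, and 3164 of the 4724 slopes. The cause was not tested for any change below except where a stricter threshold or fewer libraries made it by construction. At adjusted p under 0.01 there were 824 genes at 250 ng/mL, 547 at 750, 5597 at 1295 and 3 with a slope. With a 2-fold minimum there were 450, 349, 1930, 3010 between 1295 and 750 ng/mL, and 517 with a slope. With only the 2 compared groups in the fit, 813 genes were called at 750 ng/mL. DESeq2 called 5 genes between 750 and 250 ng/mL, where the reported count was 0. Slope calls numbered 547 with dose rank and 8 with the log2 of (dose/250 + 1). Overlaps in the same direction were 444 (p under 0.01 in both) and 278 (2-fold in both) for 250 and 750 ng/mL, 60 and 38 for 250 and 1295 ng/mL, and 52 and 26 for 750 and 1295 ng/mL.

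For each comparison of 2 groups, only the 6 libraries of those groups were left out, plus 750 ng/mL replicate 3 at 250 and 1295 ng/mL. The other libraries also enter the fit, so the full ranges could be wider. Leaving out 1 library gave 1069 to 3051 genes at 250 ng/mL, where 3051 is without 750 ng/mL replicate 3, 1105 without 0 ng/mL replicate 1 and 1069 without 250 ng/mL replicate 3. At 750 ng/mL it gave 631 to 1354, with 631 without 0 ng/mL replicate 1, 885 without 750 ng/mL replicate 1 and 837 without replicate 3. At 1295 ng/mL it gave 6519 to 9607, between 750 and 250 ng/mL 0 to 1 (1 without 750 ng/mL replicate 3), between 1295 and 750 ng/mL 9599 to 11452, and across doses 10049 to 12409. The slope gave 2 to 6172, with 2, 125 and 4 without 1295 ng/mL replicates 1, 2 and 3, 2690 without 250 ng/mL replicate 1 and 2915 without replicate 2. Without 1295 ng/mL replicate 3, cryba1a at 1295 ng/mL was at -0.10 (range -0.10 to 8.52 over libraries left out) and the slope of crybb3 at -0.17 (range -0.17 to 3.44). With a correlation estimated for each list, camera called 0 lists at 250, 0 at 750, 1 at 1295, 0 between 750 and 250 and 0 between 1295 and 750 ng/mL, against 23, 23, 27, 13 and 27; fry called 0 between 750 and 250 ng/mL. Leaving out 1 library kept 22 to 23, 21 to 23, 24 to 27, 9 to 13 and 26 to 27 of these lists. The liver list, not called at 250 or 750 ng/mL, passed with the opposite sign at both without 0 ng/mL replicate 2.

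A replicate block gave 1940, 1275, 8374, 0, 10852 and 11304 genes in the order of the comparisons above and 2187 with a slope. Over all tested genes, deviations from the group means showed no general pairing by replicate number. Of 18 same-number pairs 3 correlated above 0.1 (range -0.211 to 0.135), and 0 libraries were closest to their own number in every other group. A replicate effect on a smaller set of genes was not tested. Of 525 values of 195 named genes, 96 changed their call under at least 1 setting. DESeq2 gave 520 values with 5 calls lost and 19 gained, limma-voom 9 lost and 1 gained, only the 2 compared groups 21 lost and 4 gained of 513, the block 10 lost (among them the slope of crybb3, at 2.06) and 2 gained, RLE factors 4 and 4, and total counts 13 and 7. Of 3186 values with 1 library left out, 2999 were the same, 169 calls were lost, 16 gained and 2 reversed. Depth limits the lowest genes: lepb at 0.118 CPM in controls rests on few counts per library.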

Other observations

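The length classes, the scaling and the wrong-label tests were chosen only after the result was seen; the shared-control test and the splits of the samples were planned. The crystallin genes cryba1a and crybb3 stood out in 1 library. In 1295 ng/mL replicates 1, 2 and 3, cryba1a was at 0.248, 0.659 and 358.2 CPM, and crybb3 at 0.248, 0.329 and 18.4 CPM. At 250 ng/mL the means of these genes were 0.658 and 0.80 CPM. Without that library the log2 fold change of cryba1a at 1295 ng/mL was -0.10 and the slope of crybb3 was -0.17, so their calls rest on it. No explanation was tested.

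Classes of genes were written from textbook knowledge of transcript length and tissue, without measured lengths, and some of their genes also stand in the lists of the report. At 1295 ng/mL, 85 of 95 long genes of the nervous system and retina fell (median -1.03) and 71 of 101 short ones fell (median -0.61). Outside the nervous system, 76 of 160 long genes fell (median -0.34) and 97 of 133 short genes, mostly of general cell machinery, rose (median 0.41). At 250 ng/mL the medians were 0.24 for long and 0.10 for short nervous system genes, and 0.11 and -0.25 for long and short other genes, where 34 of the 133 short other genes fell and 0 rose. At 750 ng/mL long genes lay below short ones instead. The medians there were 0.0397 for long and 0.232 for short nervous system genes, and -0.128 and -0.0707 for long and short other genes.

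At 1295 ng/mL gene groups moved in opposite directions, nervous system genes down and ribosomal protein genes up. A scaling factor shifts all genes of a library alike and so cannot set groups apart: the neuron and synapse median lay -0.894 from the all-gene median and the ribosomal protein median 0.635 above it, the values nearest to 0 over TMM, RLE and total counts, which hardly differ here by construction and add no support of their own. Loss of long transcripts is argued against as the whole cause of the fall of nervous system genes, because short ones lay below short other genes by a difference of medians of -1.02 (permutation test, two-sided p = 1e-05, the smallest these permutations can give). It may account for other parts: long other genes lay below short other genes by -0.741 and ribosomal protein genes lay only 0.214 above short other genes (permutation p = 1e-05 each, again the smallest possible), but the short other genes are mostly general cell machinery, so length and function could not be separated. The permutation tests moved genes between the classes. Genes measured in the same libraries are not independent replicates, so these p-values do not measure the spread between samples. A response to the dose itself stays open and was not tested apart from scaling and the loss of long transcripts.

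The changes at 250 and 750 ng/mL were alike. Gene-by-gene noise in the controls shared by both comparisons is argued against as the whole cause. The covariance of the log2 fold changes was 0.116, and the highest of 50 simulated experiments gave 0.026. The simulation drew each gene on its own and held no joint shift of the control libraries, so such a shift stays open. A wrong label of 1 library across the line between these 2 doses and the other groups is argued against too, because 0 of 12 libraries were closest to a library across that line. Only the nearest library was used, so 2 libraries mislabelled together stay open. Control replicate 2 correlated at 0.98323 with 750 ng/mL replicate 1, and at 0.9831 and 0.98669 with control replicates 1 and 3. A swap between 250 and 750 ng/mL would not show in this test and stays open. A shared response to both doses may account for the likeness, as a hypothesis found and tested on the same data.

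Other splits of the samples were counted. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2269 genes at 250 ng/mL (highest other 0), 1367 at 750 (0), 8848 at 1295 (2) and 11239 between 1295 and 750 ng/mL (0), each being 1 of 10, and 0 between 750 and 250 ng/mL, which all 10 of 10 splits gave; by edgeR's quasi-likelihood test 1681 genes there had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. Over 100 splits of the 12 libraries, the real split gave the most genes across doses (11918, highest other 9620). It also gave the most slopes (4724, highest other 1670). Each was 1 of 100, the smallest share these splits can give. That argues against a random grouping of the libraries, but it cannot tell dose from another difference between the groups. Which splits called up to 9620 genes was not examined, so it was not tested whether they kept the 1295 ng/mL libraries together.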
